A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

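The data were binding sites of 5 Pumilio (Puf) proteins of *Saccharomyces cerevisiae*, from 1 CLIP (crosslinking and immunoprecipitation) library per protein, and mRNA-seq of 2 samples labelled puf3Δ. Per the labels, Puf1 (gene JSN1), Puf2, Puf4, Puf5 (gene MPT5) and Puf6 each carried a TAP tag in a strain of mating type a. Cells were grown in synthetic medium at 30 °C with 200 µM 4-thiouracil and irradiated 4 times with 365 nm light at 150 mJ/cm2, per the labels' protocols. Lysates were treated with RNase T1, the tagged protein was captured on IgG beads, and the RNA in the protein's band was sequenced. The mRNA-seq strain was BY4742 with the PUF3 gene labelled as deleted, and its polyA RNA came from extract depleted of ribosomes. No untagged, uncrosslinked or wild-type library was used here, so no background level was subtracted from any value.

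For CLIP, the authors deposited a list of called sites per library with position, strand, gene name, feature class and RPM (reads scaled to the depth of the library). CASAVA 1.8.2, Bowtie 0.12.7 and the sacCer3 genome build were named for these samples, per the submitters' processing notes. The caller, its threshold, the annotation of the untranslated regions (UTRs), the treatment of reads that map to several places, and which reads the RPM divisor counts were not given in the sources used here. Identical RPM at copies of rRNA, tRNA and Ty elements showed that reads were placed at more than one copy. In Puf6, coding sites of TEF1 and TEF2 also had the same RPM (63.53) and length. Similar genes may thus be called bound from the same reads. RPM values did not fall on steps of whole reads, so read counts, intervals of RPM and floors were not computed. For mRNA-seq, the authors deposited 1 RPKM column for both samples, made with Bowtie 0.12.7 and sacCer3, per the submitters' processing notes. How the 2 replicates were joined was not given in the sources used here.

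Gene symbols, biotypes and bounds came from a RefSeq gene table of the same assembly, which holds no UTRs. Of 6550 genes in the RPKM table, 5893 matched it by locus tag. Whether the deposited positions count from 0 or from 1 was not given in the sources used here, so positions are printed as deposited and positions within rRNA are good to 1 nt. A protein-coding gene was called bound by a protein when at least 1 site in the coding sequence, an intron or a UTR carried its name. The background for tests was 5521 protein-coding genes with an RPKM of at least 1. That RPKM table describes a strain of the other mating type, labelled as deleted for PUF3, so it stands only approximately for the mRNA levels of the CLIP strains.

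Shares of sites have exact Clopper-Pearson 95% intervals, and shares were compared between libraries by Fisher's exact test, two-sided. Overlap of bound genes was tested for the 10 pairs of proteins by Fisher's exact test. Site overlap, at least 1 nt on the same strand, was set against 1000 random placements of the sites of one protein within the same gene, one-sided, with 0.001 as the smallest possible p. Gene bounds were widened to the outermost called sites of the gene. Levels of bound and other genes were compared as medians of log2(RPKM + 1), pseudocount 1, by a two-sided permutation test with 100000 resamples of genes. For 22 gene lists fixed by name, Fisher's exact test, two-sided, compared bound genes in a list with the background. These p-values were adjusted by Benjamini-Hochberg within their family (10 pairs, 5 libraries, or 110 list tests), with 0.05 as the threshold. List differences between proteins were adjusted over all pairs and lists, and correlations of site RPM with RPKM over all libraries and site classes. The tests of snoRNA class and of each protein's own mRNA were not adjusted. Intervals and tests cover counting error alone, and with 1 library per protein they compare these libraries, not the proteins under repeated experiments.

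Gene lists, gene overlap and the rule for named genes were fixed before the data were examined, as was an alternative that compares genes within 10 RPKM bins (Cochran-Mantel-Haenszel chi-square test). After the bin results were seen, a further list test was added because bins are coarse for the most abundant mRNAs. It sets the number of bound genes in a list against the number expected from a logistic curve of binding on RPKM, cubic in log2 RPKM, with an exact Poisson-binomial p. This expected number is given beside many of the list results. Genes of the tested list took part in the fit. A list that fills much of the top of the RPKM range can thus pull the expected number towards its own count. Other alternatives were the 50% of sites with the highest RPM, 899 sites from each library, no RPKM filter or a minimum of 10, a pseudocount of 0.1, sites in the 3' UTR alone, and an overlap of 50% of both sites. Alternatives added after the data were seen were placement within the same feature of the gene, repeat copies counted once, mRNA sites alone, and the omission of Ty genes or of genes that overlap RNA genes. For placement within a feature, UTR bounds were the outermost sites called in any library, since the gene table holds no UTRs. Repeat copies were counted once for shares of sites, and not for gene lists or gene overlap.

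Text names, for each protein, the 10 protein-coding genes with the highest site RPM and up to 3 of the strongest-bound genes of each list past the threshold. The rule set 3 for each such list, and not all of them are printed. It also names the 10 genes bound by all 5 proteins with the best average rank, the bound members of the lists of single targets and PUF family genes, PUF3, and the 5 genes of highest RPKM. Sites in rRNA, snoRNAs, tRNAs, unannotated regions and mating type genes were chosen after their values were seen.

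The tests were tried on simulated data with known answers. For a list of 60 abundant genes among 5521 with no effect, Fisher's exact test called 96.5% of 200 simulated libraries, the RPKM bins 6.5% and the RPKM curve 2.5%. With a planted odds ratio of 4, these tests called 100%, 100% and 98.5% of the libraries. Binding in these libraries followed a logistic curve of log2 RPKM, a form the RPKM curve can fit, with genes independent. The rates of false calls need not hold for real libraries. The list was drawn across the RPKM range with more weight on abundant genes. The 98.5% thus need not hold for lists at the top of that range. For the overlap of bound genes, 100 pairs of independent libraries were simulated per pair of proteins, with binding set by RPKM alone. Site placement called 4% of 200 simulated sets of random sites and 100% of sets with copied sites. These sets spread sites evenly over genes of equal length, with no UTRs, so the 4% need not hold for real sites. The difference of medians called 0% of 40 simulated groups without a shift and 100% with a shift of 1 on the log2 scale.

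Analyses of RNA sequence elements were planned and not run, since no genome sequence was used here. These are the shares of sites with TGTA and related motifs, the spacing of TGTA to TA, and hexamers. Agreement of the mRNA-seq replicates, and every alternative that leaves one of them out, was planned and not run, since the RPKM values are pooled. The planned list of non-mRNA RNAs was reported as shares of sites and not tested, since its members are not protein-coding genes. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.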

Results

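RNAs bound by 5 Puf (Pumilio) proteins, which bind short elements in mRNAs, were measured by CLIP in growing yeast. Each of Puf1, Puf2, Puf4, Puf5 and Puf6 had 1 library, so no difference between them had a replicate check. Pooled mRNA-seq of 2 samples labelled puf3Δ gave the level of each mRNA. Read totals of the libraries were not used here. The RPM of all called sites summed to 889089 in Puf1, 838474 in Puf2, 898509 in Puf4, 841836 in Puf5 and 420222 in Puf6. Sums count a read at each copy of a repeat where it was placed.

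The first question was which mRNAs each protein bound. Puf1 and Puf2 had their strongest mRNA sites in the 3' UTR of PMA1, which encodes the proton pump of the plasma membrane. These sites reached 28212 RPM in Puf1 (sacCer3, chromosome VII, 479428 to 479455, minus strand) and 14973 RPM in Puf2 (chromosome VII, 479470 to 479495). Puf4 was strongest in the 3' UTR of TDH3, a glycolytic dehydrogenase, with 49293 RPM (chromosome VII, 882727 to 882750, minus strand). The strongest mRNA site of Puf5 lay in the 3' UTR of the histone H2A gene HTA1, with 40659.5 RPM (chromosome IV, 915971 to 915994, plus strand). In Puf6, mRNA sites were far weaker by this measure, and outside genes that overlap RNA genes the highest was in the coding sequence of PDC1, a pyruvate decarboxylase, with 95.6 RPM.

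PMA1 mRNA held 21 called sites in Puf2 and 8 in Puf1. Puf1 also had strong 3' UTR sites in TDH3 (26925 RPM), HOR7 (16522 RPM), the cell wall gene HSP150 (12272 RPM), CWP2 (10679 RPM), TEF1 (7407 RPM) and YDR524C-B (7377 RPM). Its sites in SOD1 (12120 RPM), the polyamine transporter gene TPO2 (8413 RPM) and ENO2 (7476 RPM) were classed as 5' UTR. Puf2 was strong in LSP1 (8048 RPM), TDH3 (7626 RPM), TPO2 (6837 RPM), SED1 (6118 RPM), YNL190W (5470.3 RPM), MRH1 (4874 RPM), HSP150 (4572 RPM), YRO2 (4218 RPM) and RPI1 (4031 RPM). Puf4 had 14016 RPM in NIP1, a translation initiation factor subunit, 10548 RPM in ILV5, 7702 RPM in the histone H4 gene HHF2 and 6813 RPM in the phosphate transporter gene PHO84. The next in Puf4 were HHT2 (5983 RPM), ATP1 (5671 RPM), RPL39 (5439 RPM), RPS19B (5214 RPM) and SUP45 (5202 RPM). For Puf5, RPS27A (12395 RPM), SUN4 (9799.8 RPM), IXR1 (9789 RPM), HHF2 (8615 RPM) and RPL27B (6895 RPM) followed HTA1. TOS1 (5471 RPM), NCW1 (4841 RPM), YDR524C-B (4341 RPM) and RPL28 (4288 RPM) completed the 10 strongest of Puf5. In Puf6, YLR154C-G (18387 RPM), YGL088W (749 RPM) and YJL047C-A (212 RPM) overlap RNA genes on the same strand. PDC1 was followed there by ALO1 (95.1 RPM), RPS6B (94.0 RPM), MFA2 (93.6 RPM), COX19 (93.4 RPM), MBF1 (89.5 RPM) and GUF1 (88.4 RPM).

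The lists held 899 sites for Puf1, 1949 for Puf2, 3002 for Puf4, 3361 for Puf5 and 1369 for Puf6. They named 348, 677, 1118, 1435 and 386 protein-coding genes. Of the 5521 background genes, 3193 had no site of any protein and 1424 had sites of 1 protein. Puf5 alone bound 653 background genes, Puf4 alone 429, Puf2 alone 179, Puf6 alone 90 and Puf1 alone 73. Sites of all 5 proteins were found in 40 genes. By average rank, TDH3, HSP150, CCW12, CWP2, DSE2, SED1, MFA2, YEF3, PMA1 and FAS1 led these 40, and 5 of them (HSP150, CCW12, CWP2, DSE2 and SED1) encode cell wall proteins. The TDH3 site at 882727 to 882750 was called with the same bounds in Puf1, Puf4 and Puf5, where it had 2937 RPM.

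The next comparison asked where in the transcript the sites lay. Puf5 sites lay in 3' UTRs most often, with 39.7% of its sites (95% interval 38.1 to 41.4). Shares were 21.6% (18.9 to 24.4) in Puf1, 17.99% (16.6 to 19.4) in Puf4, 17.1% (15.4 to 18.8) in Puf2 and 6.28% (5.06 to 7.70) in Puf6. Of 10 pairs, only Puf2 with Puf4 did not differ past the threshold (odds ratio 0.940, adjusted p = 0.423, Fisher's exact test). The largest odds ratio was that of Puf5 over Puf6, 9.83 (7.80 to 12.5, adjusted p = 2.9e-136, Fisher's exact test). With mRNA sites alone it was 5.88 (adjusted p = 5.3e-53, Fisher's exact test), while Puf2 over Puf6 went from 3.07 to 1.95 and Puf4 over Puf6 from 3.27 to 1.76. Among sites in mRNA, coding sites made up 65.3% in Puf4 and 70.8% in Puf6, against 31.3% in Puf5. Weighted by RPM, 3' UTR sites held 58.4% of the Puf4 total, 57.8% in Puf5, 46.8% in Puf1, 35.2% in Puf2 and 0.957% in Puf6. Ty elements, retrotransposons with many near-identical copies, took 28.0% of sites in Puf1 and 13.9% in Puf5, but 1.33% and 0.777% of the RPM. With repeat copies counted once, the 3' UTR share rose to 35.3% in Puf1, 49.9% in Puf5 and 11.02% in Puf6.

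**Figure D1:**
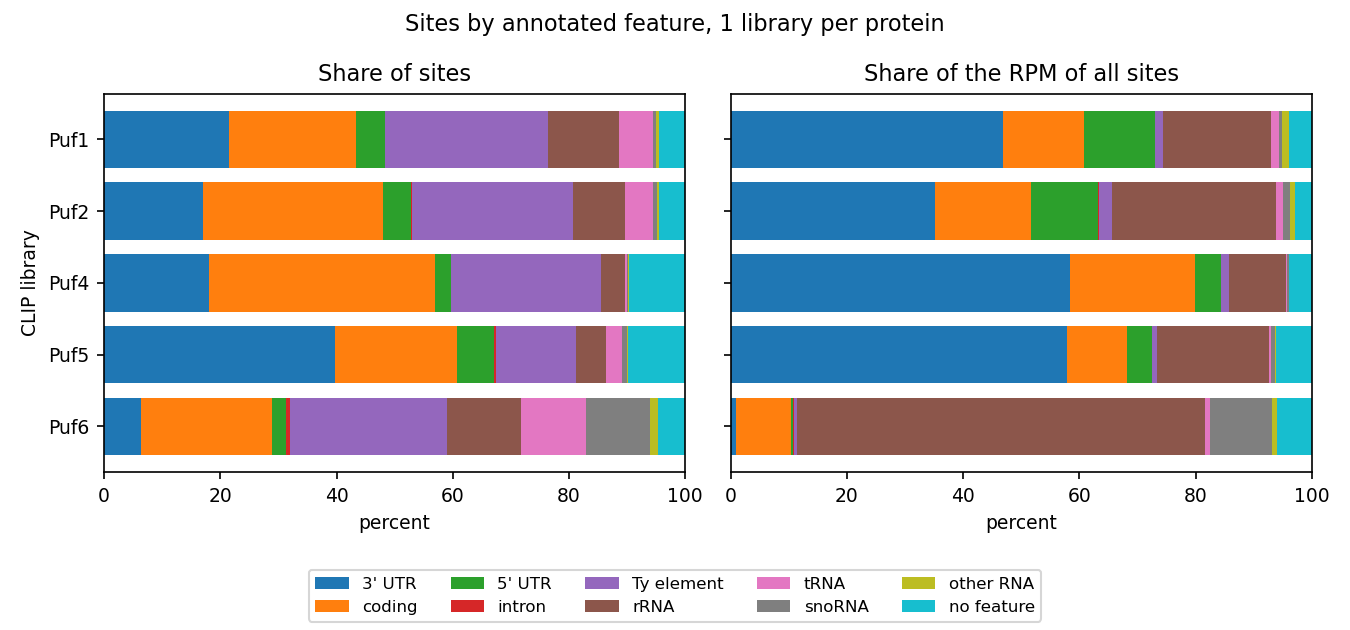
Stacked bars give the percent of called sites (left) and the percent of the RPM of all sites (right) in each annotated feature, for 1 CLIP library per protein. Sites in 3' UTRs make up 39.7% of Puf5 sites, and rRNA holds 70.1% of the RPM of Puf6, summed over the rDNA copies.

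Puf6, a nucleolar protein, was compared with the other libraries on stable RNAs. Its sites in rRNA held 70.1% of its RPM, against 9.78% in Puf4 to 28.2% in Puf2. These shares sum over the rDNA copies. With copies counted once, 85 of the 175 Puf6 sites in rRNA remained, and the RPM share was not computed that way. On 1 rDNA copy, Puf6 sites summed to 130147 RPM in 25S rRNA, the large subunit RNA, and to 7575 RPM in 18S rRNA. The 25S to 18S ratio was 17.2, and those of the other 4 libraries ran from 0.641 to 1.02. Called Puf6 sites covered 2386 nt of 25S and 1023 nt of 18S rRNA, with a mean of 3517 RPM per 25S site and 303 RPM per 18S site. Mean RPM per site gave a ratio of 11.6 in Puf6 and of 0.229 to 0.577 in the others. Within 25S rRNA, 28.5% of the Puf6 RPM fell in 1 site near positions 1593 to 1623 (chromosome XII, 453559 to 453589, minus strand), with 37150.3 RPM. The second was near positions 1683 to 1719, with 18387 RPM. In Puf1 the strongest 25S site lay near positions 2919 to 2937 and in Puf2 near 1983 to 2012. It lay near 69 to 97 in Puf4 and near 2967 to 2994 in Puf5. Weaker sites overlapped the first Puf6 site in Puf5 (1865 RPM), Puf4 (684 RPM) and Puf1 (228 RPM), and none did in Puf2. The second Puf6 site was overlapped in Puf2 (3742 RPM), Puf5 (2167 RPM) and Puf4 (916 RPM), and not in Puf1. ITS2, the spacer removed from the precursor next to 25S rRNA, held 3 sites classed as such with 7092 RPM in Puf6 and 0 in the other 4 libraries. Sites classed as the whole precursor held 10579.9 RPM in Puf6, 6685 RPM in Puf2, 1789 RPM in Puf1, 683 RPM in Puf4 and 269 RPM in Puf5. In Puf6 the strongest of these (5174 RPM) covered 18 nt of ITS2 and 7 nt of 5.8S rRNA. In Puf2 the strongest (3677 RPM) covered 20 nt of 5.8S rRNA and 1 nt of ITS2. Sites classed as ITS1 held 670.2 RPM in Puf6.

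**Figure D2:**
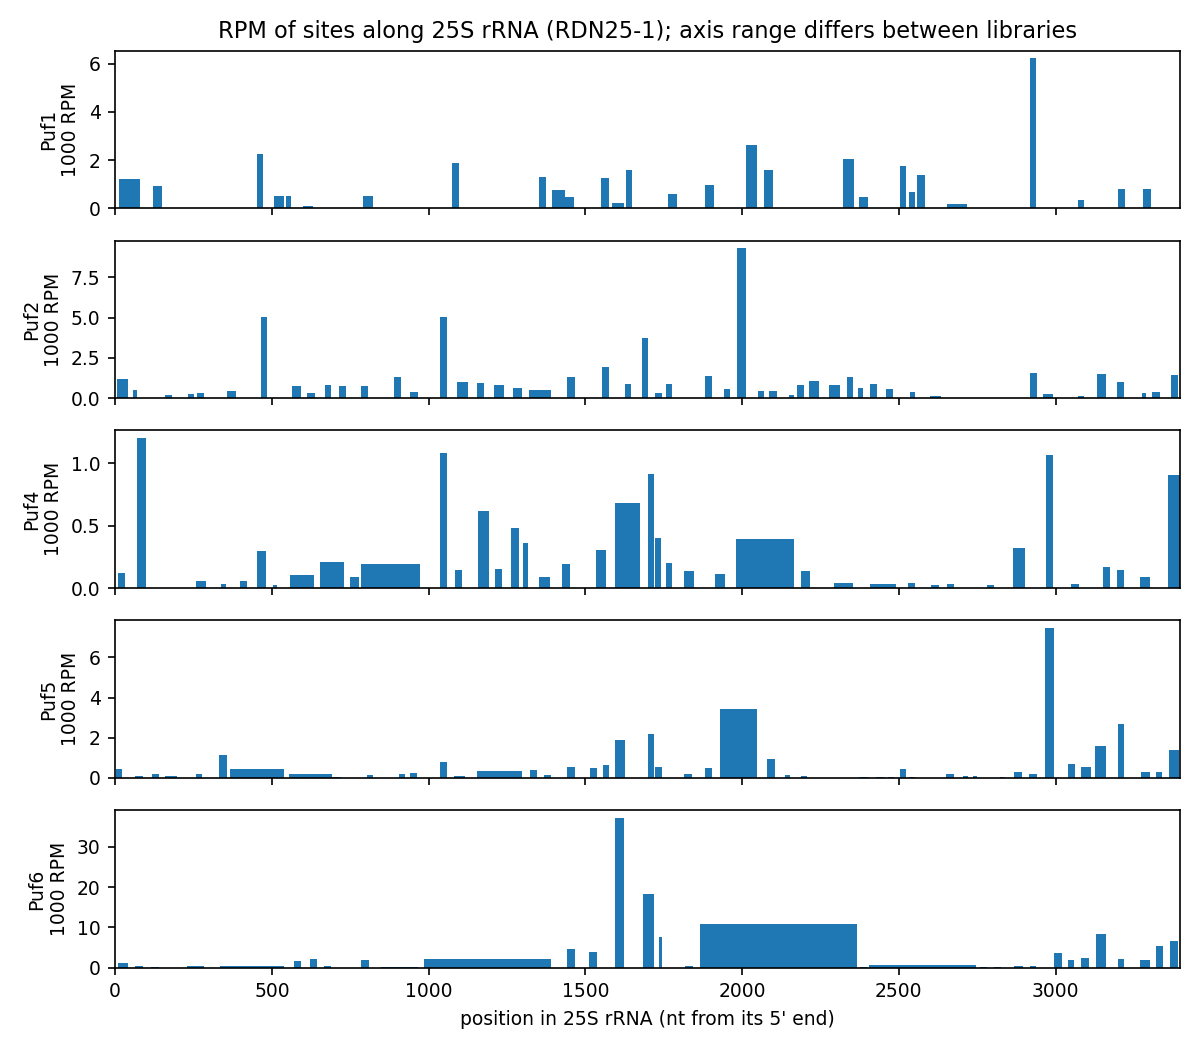
Bars span each called site along 25S rRNA, in nt from its 5' end, and their height gives its RPM (axis in units of 1000 RPM), with a separate axis range for each of the 5 libraries. The highest Puf6 bar, near positions 1593 to 1623, reaches 37150.3 RPM.

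Small nucleolar RNAs (snoRNAs), which guide rRNA modification, were also frequent in Puf6. They took 150 of its sites, 10.96% (9.35 to 12.7), against 0.233% in Puf4 to 0.922% in Puf5. Against Puf5, the nearest library, the odds ratio of Puf5 over Puf6 was 0.0757 (0.0494 to 0.113, adjusted p = 1.1e-52, Fisher's exact test). Sites were present in 65 of 76 snoRNAs in Puf6, in 25 in Puf5, 12 in Puf2, 7 in Puf4 and 5 in Puf1. Per snoRNA with a site, the median of the strongest RPM was lower in Puf6 (199 RPM) than in Puf2 (791 RPM), Puf1 (695 RPM) and Puf4 (428 RPM), and in Puf5 it was 137 RPM. Puf6 also had the lowest median RPM over all sites, 27.8 RPM. SNR3 (3926 RPM), SNR63 (2166 RPM), SNR9 (1952 RPM), SNR191 (1522 RPM) and SNR13 (1200.5 RPM) were the strongest in Puf6. Transfer RNAs held 11.1% (9.49 to 12.9) of Puf6 sites, 5.90% (4.45 to 7.64) of Puf1 sites and 0.2998% (0.137 to 0.568) of Puf4 sites, with no test. With repeat copies counted once these shares were 6.32%, 1.48% and 0.262%. By RPM the order differed, with tRNAs at 1.30% in Puf1, 1.19% in Puf2, 0.894% in Puf6 and 0.153% in Puf4. Among tRNAs the strongest site was in tE(CUC)I in Puf1 (1962 RPM) and in tL(UAG)J in Puf6 (666 RPM).

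Shared bound genes were compared for the 10 pairs of proteins. Genes bound by one Puf were more often bound by another in all 10 pairs. With all sites the largest odds ratio was that of Puf1 with Puf2, 6.62 (5.17 to 8.47), with 136 shared genes against 38.0 expected. The smallest was that of Puf5 with Puf6, 3.82 (3.05 to 4.79), with 188 shared genes against 88.0 expected. With 899 sites from each library, Puf4 with Puf5 rose from 3.84 to 7.39 and Puf1 with Puf2 was at 7.34, so this order held for libraries of unequal size. With 3' UTR sites alone the odds ratios ran from 6.50 (Puf1 with Puf4) to 16.1 (Puf1 with Puf2). Puf4 and Puf5 shared the most genes, 523 against 273 expected (adjusted p = 3.0e-76, Fisher's exact test). TDH3, PMA1, HSP150 and SED1 were among the genes shared by every pair. Within RPKM bins the odds ratios ranged from 2.17 (1.77 to 2.65) for Puf2 with Puf4 to 2.72 (1.99 to 3.72) for Puf1 with Puf6. Independent libraries simulated from RPKM alone gave medians of 1.10 to 1.54 in the same bins, so the bins left part of the effect of abundance. All 10 observed values lay above the highest of their own 100 simulated runs.

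**Figure D3:**
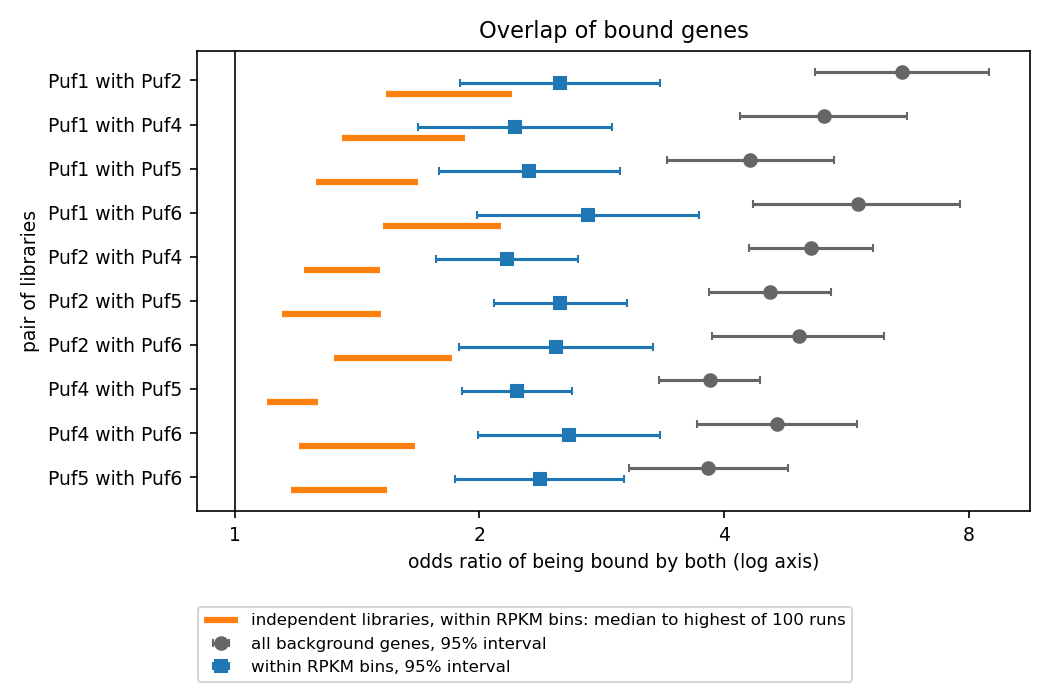
For each pair of libraries, the log axis gives the odds ratio of being bound by both over all background genes (circles) and within RPKM bins (squares) with 95% intervals, and orange bars run from the median to the highest of 100 simulated independent pairs. Puf1 with Puf2 falls from 6.62 to 2.51 within RPKM bins.

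The following comparison asked whether proteins that bound the same mRNA did so at the same place. HSP150 gave an example, with 3' UTR sites ending at position 121989 on chromosome X in Puf1, Puf2, Puf4 and Puf5. CCW12 was called at 370096 to 370116 on chromosome XII, in the 5' UTR, in Puf1, Puf2 and Puf5. Lysates of all libraries were treated with RNase T1, so shared ends may come from where it cuts and need not show shared binding. Random placement considered neither RNase cutting nor RNA sequence, so the folds given here may be too high. Of 430 Puf1 sites, 21.4% (17.6 to 25.6) overlapped a Puf2 site, against 7.35% under random placement in the gene, a fold of 2.91. Of 1772 Puf4 sites, 13.8% (12.2 to 15.5) overlapped a Puf5 site, a fold of 2.98. Folds of the 10 pairs ran from 1.36 (Puf6 in Puf4, n = 433 sites, adjusted p = 0.013) to 3.39 (Puf1 in Puf5, n = 430 sites, p = 0.001, the smallest possible). Placement within the same feature of the gene took UTR bounds from the outermost called sites, which narrows the room for placement. The overlap of placed sites then rose, for Puf1 in Puf5 from 6.66% to 21.4%, so these folds depend on where sites were called. When sites were placed in this way, the call ended in 5 pairs (Puf1 in Puf4, in Puf5 and in Puf6, Puf2 in Puf4, and Puf6 in Puf4). It stayed in the other 5, with folds of 1.18 for Puf4 in Puf5, 1.29 for Puf2 in Puf5, 1.29 for Puf6 in Puf2, 1.36 for Puf1 in Puf2 and 1.40 for Puf6 in Puf5.

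Functional groups of bound genes were then compared with the background. Nutrient transporters of the plasma membrane were bound more often than their mRNA levels predicted in Puf1, Puf2 and Puf5, cell wall genes in Puf2, Puf5 and Puf6, and cytosolic ribosomal protein genes in Puf4 and Puf5. Genes of mitochondrial assembly and import were bound by Puf4 in fewer cases than predicted, while Fisher's exact test, which uses no prediction, did not call them. The prediction used RPKM of the strain labelled puf3Δ. Whether the levels of these genes differ between that strain and the CLIP strains was not tested. Before mRNA level was considered, 30 of 110 tests called a list as bound more often (Fisher's exact test). Within RPKM bins 14 of the 30 calls remained, and against the number expected from the RPKM curve 8 remained. None of these list tests considered gene length. Genes bound by one protein of a pair alone were also compared with those bound by the other alone (Fisher's exact test). No list passed the threshold there, the lowest adjusted p being 0.168 for cytosolic ribosomal proteins in Puf4 over Puf6. Genes bound by both were left out, so this does not show that the proteins bind these lists alike.

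Transporter genes with a Puf1 site numbered 11 of 68, against 4.19 expected from RPKM (adjusted exact p = 0.0333). They included TPO2 (8413 RPM), the purine permease gene FCY2 (5994 RPM) and the hexose transporter gene HXT7 (1871 RPM). Puf2 bound 17, against 8.07 expected (adjusted exact p = 0.0333), led by TPO2, TPO3 (2074 RPM) and MUP1 (861 RPM). Puf5 bound 29, against 17.0 expected (adjusted exact p = 0.0333), led by HXT7 (632 RPM), AGP1 (603 RPM) and FUI1 (506 RPM). Counting 3' UTR sites alone ended the call of Fisher's test for Puf2 (adjusted p = 0.332) and Puf5 (adjusted p = 0.446).

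Cell wall genes with a Puf6 site numbered 21 of 61, against 8.48 expected (adjusted exact p = 0.00187), among them CRH1 (83.2 RPM), DSE4 (73.5 RPM) and CCW12 (71.7 RPM). Puf5 bound 36, against 25.0 expected (adjusted exact p = 0.0333), led by SUN4, TOS1 and ECM33 (3186 RPM). Puf2 bound 27, against 17.2 expected (adjusted exact p = 0.0333), led by SED1, HSP150 and the chitinase gene CTS1 (3437 RPM). In Puf1 (10 genes, 9.52 expected, adjusted exact p = 1) and Puf4 (29 genes, 24.3 expected, adjusted p = 0.465) the call ended once RPKM was considered. HSP150, CWP2 and SED1 were strongest for Puf1, and DSE2 (3432 RPM), HSP150 (2773 RPM) and PIR1 (2525 RPM) for Puf4. No mRNA site of Puf6 exceeded 95.6 RPM outside genes that overlap RNA genes. Without an untagged library, the cell wall call in Puf6 could not be told apart from background common to the libraries.

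Of 137 cytosolic ribosomal protein genes, Puf4 bound 114 (odds ratio 22.3, 14.1 to 36.9), against 97.2 expected from RPKM (adjusted exact p = 0.0259). This p takes genes as independent, while similar genes may share reads, and no list was tested with copies counted once. RPL39, RPS19B and RPL9B (5015 RPM) had the strongest sites. Puf5 bound 106, against 89.9 expected (adjusted exact p = 0.0333), led by RPS27A, RPL27B and RPL28. For Puf1 (55 genes, 47.4 expected), Puf2 (85 genes, 76.6 expected) and Puf6 (39 genes, 37.9 expected) the adjusted p was 0.439, 0.411 and 1. The planned chi-square test in RPKM bins kept this group in Puf1 (odds ratio 2.23, adjusted p = 0.00225) and Puf2 (2.21, adjusted p = 0.0020), and not in Puf6 (adjusted p = 0.123). The strongest there were RPL24B (2914 RPM), RPS7B (2874 RPM) and RPL30 (2802 RPM) in Puf1, RPL23B (1960.1 RPM), RPL40A (1913 RPM) and RPL33A (1899 RPM) in Puf2, and RPS6B, RPL4A (79.0 RPM) and RPL28 (75.9 RPM) in Puf6. Mitochondrial assembly and import genes numbered 10 of 83 in Puf4, against 20.1 expected (adjusted exact p = 0.0432), while Fisher's test did not call them (odds ratio 0.552, adjusted p = 0.235).

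All 10 histone genes had a Puf5 site (lower bound of the odds ratio 6.76), but 6.12 were expected from RPKM and the adjusted p was 0.0988. Puf4 bound 8 of the 10, against 6.60 expected (adjusted exact p = 0.751). HHF2, HTB1 (4758 RPM in Puf4 and 2660 RPM in Puf5) and HHT2 were among the strongest in Puf4, and HTA1, HHF2 and HTB1 in Puf5. Glycolysis and fermentation genes were called in all 5 libraries by Fisher's test, and in none against the RPKM curve. Puf4 bound 20 of 25 of them (16.5 expected, adjusted exact p = 0.272) and Puf1 bound 11 (11.04 expected, adjusted p = 1), with TDH3, ENO2, CDC19 (1782 RPM in Puf4) and PDC1 (3272 RPM in Puf1) among the strongest. The chi-square test in RPKM bins kept the glycolysis call in Puf4 (adjusted p = 0.0206) and Puf6 (adjusted p = 0.000305). For Puf6, 9.17 were expected from the RPKM curve, and GPM1 had 81.7 RPM. Glycolysis genes hold some of the highest RPKM values and took part in the fit of the curve. A call that ended against the curve thus does not show that abundance explains it.

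Translation factors, also called in all 5 libraries by Fisher's test, reached an adjusted p of 0.137 in Puf6 (13 of 46, 6.62 expected) and 0.162 in Puf4 (28 of 46, 20.7 expected) against the RPKM curve. NIP1, SUP45 and YEF3 (4764 RPM) led this group in Puf4, TIF11 (3024 RPM) in Puf2, YEF3 (2542 RPM) in Puf5, TEF1 in Puf1 and GCN1 (83.5 RPM) in Puf6. Small proteolipids and P-type ATPases of the plasma membrane were bound by Puf5 in 12 of 21 cases (6.38 expected, adjusted exact p = 0.0707) and by Puf1 in 5 (2.42 expected, adjusted p = 0.310). The planned chi-square test in RPKM bins kept the call in Puf5 (odds ratio 4.32, adjusted p = 0.0206) and not in Puf1 (adjusted p = 0.131). ZEO1 had 5386 RPM in Puf1 and 1014 RPM in Puf5. No list of mitochondrial ribosomal proteins, nucleolar ribosome biogenesis, chromatin, ergosterol synthesis, cell cycle, oxidative phosphorylation, proteasome, mRNA decay, secretory pathway, MAP kinase signalling, stress and nutrient transcription factors or bud site genes was called by any of the 3 tests. Nucleolar ribosome biogenesis in Puf4 came closest by Fisher's test, with 36 of 127 genes (odds ratio 1.63, adjusted p = 0.0625, 28.6 expected from RPKM).

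**Figure D4:**
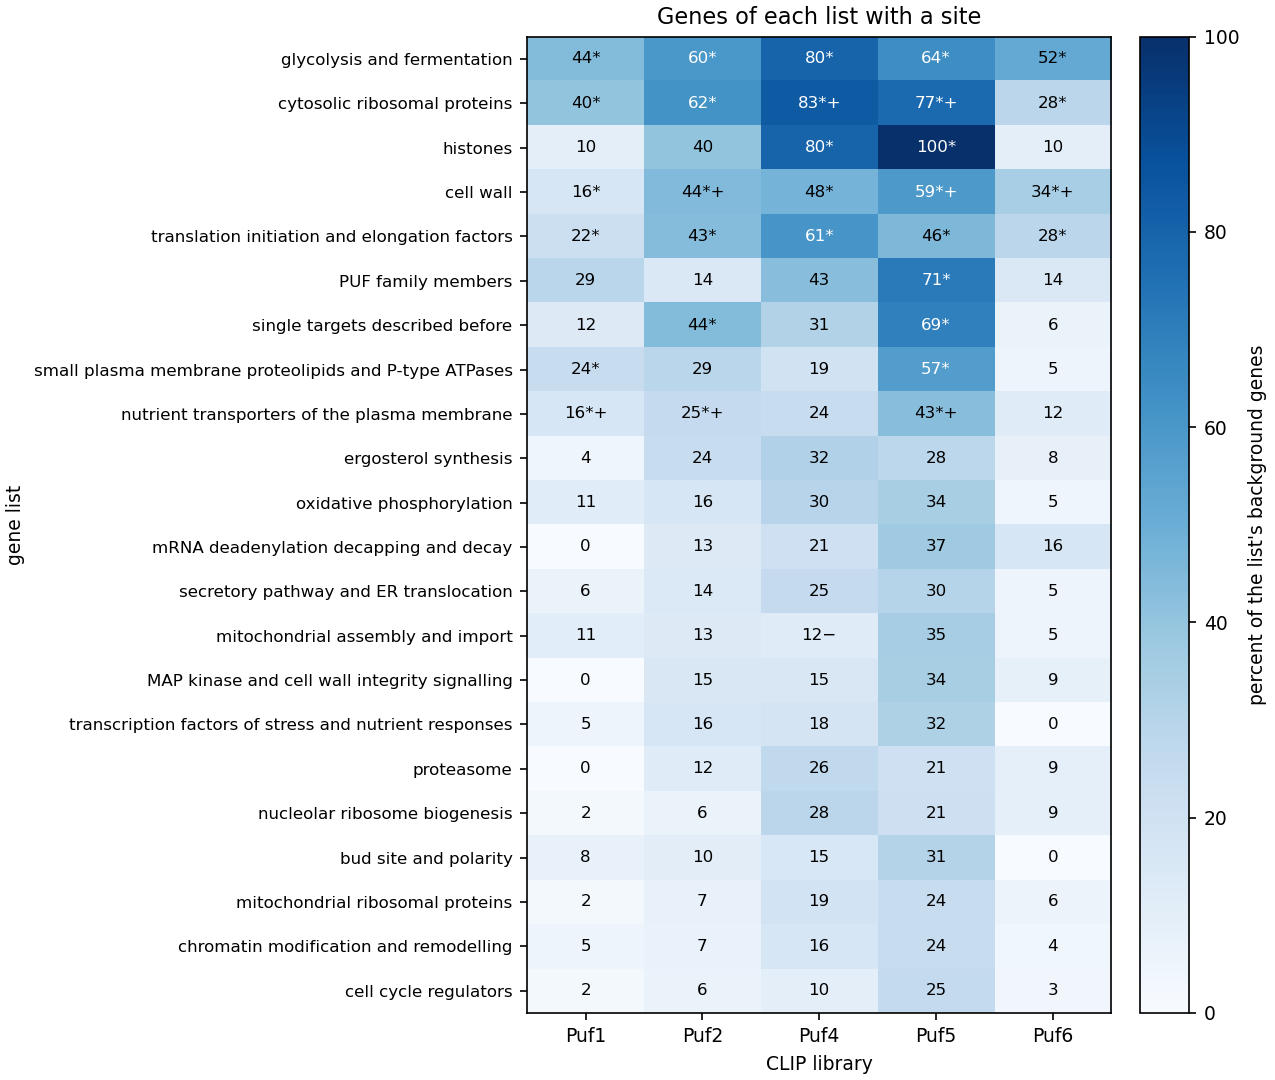
Each cell gives the percent of a list's background genes with a site in 1 CLIP library, darker for higher percents. An asterisk marks adjusted p under 0.05 in Fisher's exact test, and a plus or minus sign marks more or fewer bound genes than the RPKM curve predicts, as for Puf6 and the cell wall (21 of 61 genes, 8.48 expected).

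Single mRNAs tied to Puf proteins by earlier work formed another list. Puf5 bound 11 of 16 of these and Puf2 bound 7, but against the RPKM curve neither passed (6.82 expected, adjusted exact p = 0.214, and 4.63 expected, adjusted p = 0.524). PMP2, which encodes a regulator of the plasma membrane proton pump, had 3553 RPM in Puf2, 2017 RPM in Puf1 and 79.1 RPM in Puf5. Its paralog PMP1 had a site in Puf2 alone among the 5 lists, with 2862 RPM. PMP3 had 1481 RPM in Puf2, 145 RPM in Puf4 and 114 RPM in Puf5. The histone H3 gene HHT1 had 2608 RPM in Puf4 and 2568 RPM in Puf5, and HHT2 had 1416 RPM in Puf5. RAX2 (876 RPM) and STE7 (209.6 RPM) had sites in Puf5, and LRG1 had sites in Puf5 (248 RPM) and Puf4 (53.6 RPM). ASH1 had 217 RPM in Puf2 and 149.6 RPM in Puf5, TEC1 had 174 RPM in Puf5 and 6.56 RPM in Puf2, and TIF1 had its highest value, 346 RPM, in Puf4. No site was listed in HO, COX17, CYT2 or HXK1. The list was not split by the Puf protein tied to each mRNA, and no Puf3 CLIP library was used here. A missing site thus need not be a missed target.

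Genes of the PUF family were bound by Puf5 in 5 of 7 cases (odds ratio 7.52, 1.23 to 79.1, adjusted p = 0.0470), against 1.31 expected from RPKM (adjusted exact p = 0.0663). They were PUF4 (179 RPM), PUF3 (156 RPM), MPT5 (132 RPM), PUF6 (102 RPM) and JSN1 (19.1 RPM). Puf4 had sites in the 5' UTR of PUF4 (919 RPM), in the 3' UTR of MPT5 (539 RPM) and in PUF6 (1.22 RPM). PUF2 mRNA had 641 RPM in Puf2 and 366 RPM in Puf1, Puf1 also had 167 RPM in PUF4, and Puf6 had 64.5 RPM in PUF6. NOP9, a nucleolar relative, had no listed site. The chi-square test in RPKM bins called the family in Puf5 (adjusted p = 0.0182) and, with 2 bound genes, in Puf1 (adjusted p = 0.0309), where neither Fisher's exact test (adjusted p = 0.158) nor the RPKM curve (0.193 expected, adjusted exact p = 0.185) did. The call of Fisher's test for Puf5 ended with an RPKM minimum of 10 (adjusted p = 0.0603), with the stronger sites (adjusted p = 0.275) and with 3' UTR sites alone (adjusted p = 0.293).

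Finally, mRNA levels of bound and other genes were compared. Bound genes had higher RPKM in all 5 libraries, most in Puf1, with a median of 328 RPKM against 58.0 RPKM for other genes. On the log2(RPKM + 1) scale the medians differed by 2.48 in Puf1, 2.03 in Puf2, 1.62 in Puf4, 1.495 in Puf6 and 1.08 in Puf5 (adjusted p = 1e-05 in each, the smallest possible, permutation test). Genes are not independent replicates in this test. TDH3 (24821 RPKM), CCW12 (12774.5 RPKM), FBA1 (10020.5 RPKM), ENO2 (9899 RPKM) and CDC19 (9761 RPKM) had the highest levels. Across bound genes, the RPM of the strongest site followed RPKM weakly, with a Spearman's rho of 0.219 and a Pearson's r of 0.239 in Puf4 (adjusted p = 3.7e-05 for each) and a rho of 0.00268 in Puf6. MFA2, the a-factor gene bound by all 5 proteins, had 1.11 RPKM, and the RPKM strain is of the mating type that does not express it. PUF3 had 23.6 RPKM in the libraries labelled puf3Δ, above 19.2% of background genes.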

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

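Of the tests below, those of the 25S pattern in Puf6 and of PUF3 in the mRNA-seq, the test in RPKM and length bins and the simulation of independent libraries were chosen only after the result was seen. Sites outside annotated features were looked at apart from the comparisons, and the strongest of each library outside repeats and rDNA is given here as a signal that no comparison used. The rDNA was left out after a first look had returned rDNA fragments for Puf2 and Puf6.

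In Puf1 this site had 2242 RPM (chromosome III, 288321 to 288350, plus strand) and lay over OCA4 on the other strand. The Puf2 site had 1180.3 RPM (chromosome IV, 507853 to 507874) and lay 79 nt from the noncoding transcript SUT053. In Puf4, 2471 RPM lay 157 nt from NSA2 (chromosome V, 413210 to 413237, minus strand). Puf5 had 2764.5 RPM at 27 nt from ECM33, on the same strand (chromosome II, 394769 to 394794), between the end of its coding sequence and a Puf5 site at 394874 to 394898 classed as ECM33 3' UTR. The Puf6 site had 575.2 RPM (chromosome XVI, 776470 to 776487) and lay 634 nt from the noncoding gene YNCP0018C.

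Genes bound by one Puf were more often bound by another in all 10 pairs. Abundance as sorted into RPKM bins is not the whole cause, since 10 pairs kept a lower bound over 1, and 10 did so in bins of RPKM and gene length, with odds ratios of 1.98 to 2.51. Bins leave some abundance in place: independent simulated libraries reached 2.19 at most, and every pair lay above the highest of its own simulated runs. Whether related proteins share more targets stays open, because Puf1 with Puf2, close relatives, had a lower bound of 1.90 and an upper bound of 3.33, which lie amid those of the other 8 pairs outside Puf4 with Puf5 (highest lower bound 2.08, highest upper bound 3.72). Binding to one kind of accessible RNA, background of the CLIP procedure common to all libraries, or differences between the RPKM strain and the CLIP strains may each contribute to the values of 10 pairs in bins, and none was tested.

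The 25S rRNA held most rRNA reads in Puf6. A general rRNA background left by low capture of mRNA would raise 18S rRNA too, and the 25S to 18S ratio of Puf6 was 15.5 over both rDNA copies, against 0.60 to 0.971 in the other 4 libraries. Counting reads at several copies scales 25S and 18S rRNA alike, so it would leave their ratio, 17.2 over 1 copy, as it is. For the same reason the ratio cannot show how far this counting raised the RPM of rRNA as a whole. Binding to precursors of the large subunit stays open: sites classed as ITS2 had 7092 RPM in Puf6, more than the 670.2 RPM of sites classed as ITS1, but sites classed as the whole precursor occurred in all 5 libraries, and those of Puf2 and Puf4 reached 1 and 3 nt into ITS2. With the whole-precursor class included, Puf6 sites that reach ITS2 summed to 13967 RPM and those that reach ITS1 to 3893 RPM. Puf6 sites in ETS1, the spacer ahead of 18S rRNA, summed to 482.7 RPM. Large subunit particles that stay with the beads for other reasons were not tested.

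PUF3 had an RPKM above 0 in the libraries labelled puf3Δ. Reads placed by chance on a deleted gene stay open: LYS2, deleted in BY4742, had an RPKM of 0, but so did YDR524C-B, among the 10 strongest bound mRNAs of Puf1 and Puf5, so a 0 need not mean absence. A strain of mating type a is argued against by MF(ALPHA)1, the gene of the alpha mating type pheromone, at 1323 RPKM against 1.35 RPKM for MFA1, while another alpha strain stays open. A part of PUF3 left in the strain, or a mixed culture, cannot be told apart, because the 23.6 RPKM come without read positions.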

How the results depend on the processing

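Placement within the same feature, repeat copies counted once, mRNA sites alone, the RPKM curve and the omission of Ty genes or of genes that overlap RNA genes were chosen after seeing the data. Overlap of bound genes kept its direction and call in all 10 pairs under each of its 8 alternatives, and so did the 3' UTR odds of 9 pairs under 3 and the level of bound genes in 5 libraries under 3. Puf2 over Puf4, not called in any of these, went from 0.940 to 1.014, 1.003 and 1.104. Values of the gene overlap moved, Puf4 with Puf5 from 3.84 to 7.39 at equal numbers of sites and Puf1 with Puf2 from 6.62 to 16.1 with 3' UTR sites alone; the cause was not tested. Site overlap kept all calls with stronger sites and with an overlap of 50% of both sites. Placed within the same feature, 5 of its calls ended, at folds of 1.01 (Puf1 in Puf4), 1.05 (Puf1 in Puf5), 1.12 (Puf1 in Puf6), 1.12 (Puf2 in Puf4) and 1.03 (Puf6 in Puf4); the cause was not tested. Keeping the stronger 50% of sites left 450, 976, 1503, 1683 and 686 sites in Puf1, Puf2, Puf4, Puf5 and Puf6 by construction. The 3' UTR share in that order became 38.2, 29.3, 29.0, 54.0 and 10.2% with stronger sites, 35.3, 27.7, 27.6, 49.9 and 11.02% with repeat copies counted once, and 44.6, 32.3, 30.1, 59.0 and 19.6% of mRNA sites, the latter pair through smaller denominators; the cause of the first was not tested.

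Lists bound more often fell from 6, 6, 5, 9 and 4 to 3, 3, 2, 5 and 2 within RPKM bins and to 1, 2, 1, 3 and 1 against the RPKM curve, and lists bound less often in Puf4 rose from 0 to 1 under both. Abundance of the list's genes is built into these alternatives. Odds of translation factors in Puf5 turned to 0.941 in bins, and those of glycolysis in Puf1 to 0.993 against the curve. Of 30 list calls, 6 ended with 3' UTR sites alone, 2 with an RPKM minimum of 10 and 1 with stronger sites; none ended without an RPKM filter or without Ty genes. Motif shares, TGTA spacing, hexamers and their alternatives were not run, nor were those that leave out an mRNA-seq replicate or compare the replicates. No paired analysis was possible because each protein had 1 library and the mRNA-seq replicates were pooled. Read counts were not recovered, so the depth behind a low RPM is unknown.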

Other observations

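Of the tests below, those of snoRNA class, of the strength of 3' UTR sites against mRNA level and of each protein's own mRNA were chosen only after the result was seen. Mating type genes gave a view of the difference between the strains. The a-specific genes MFA1 (1.35 RPKM) and MFA2 (1.11 RPKM) had sites in 4 and 5 of the CLIP libraries, STE2 (5.61 RPKM) and STE6 (5.56 RPKM) in 3 each, and AGA2 (1.48 RPKM) in 1. No site was listed in BAR1 or ASG7. Among alpha-specific genes, MF(ALPHA)1 (1323 RPKM) and STE3 (261 RPKM) had sites in 2 libraries, SAG1 (736 RPKM) in 1, and MF(ALPHA)2 (196 RPKM) in none.

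Distances of 3' UTR sites from the stop codon were compared with no reference for UTR length. Median distances were 49 nt in Puf6, 60 nt in Puf4, 66 nt in Puf5, 67 nt in Puf1 and 71.5 nt in Puf2, and 51.2, 42.8, 39.2, 36.5 and 34.7% of the sites lay within 50 nt in that order. No pair passed the threshold after adjustment, the lowest adjusted p being 0.114 (permutation test). The difference of Puf4 minus Puf5 was -6 nt (95% interval -13 to 2, adjusted p = 0.297, permutation test), which leaves a shift of a few nt open.

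Among Puf6 sites on snoRNAs, 26 of 29 H/ACA and 39 of 47 C/D snoRNAs had a site. A preference for one class stays open (odds ratio 1.77, 0.378 to 11.3, p = 0.517, Fisher's exact test). How far site RPM follows the level of the mRNA stays open. The highest Spearman's rho across bound genes among the 5 libraries was 0.219, under the bound of 0.3 set before, but bound genes had higher RPKM than others, and a rho among called genes alone can be lowered by that choice. For 3' UTR sites alone rho was 0.327 in Puf4 (461 genes, adjusted p = 3.7e-05, permutation test), 0.257 in Puf1, 0.235 in Puf2, 0.233 in Puf5 and 0.106 in Puf6. For coding sites rho was -0.259 in Puf1 and 0.116 in Puf4, so the value over all sites joins relations of opposite sign in Puf1. At sites shared by Puf1 and Puf2, rho was 0.492 (0.308 to 0.641, 92 sites), while Puf1 with Puf4 gave 0.614 (0.395 to 0.766, 52 sites), so whether related proteins rank shared sites more alike stays open.

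Of the 5 libraries, 4 had a site in the mRNA of the protein itself, and Puf1 was the exception with no site in JSN1. Among the 20 pairs of a library with the mRNA of another of the 5 proteins, 7 had a site. Binding of a Puf to its own mRNA may be more frequent, but 12 of the 120 assignments of mRNAs to libraries gave as many (exact permutation test, one-sided, p = 0.1). Reads from the tagged gene's own transcript, bound while the protein is made, were not tested as a cause.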
